A study of Mus musculus with 4 samples.

How the data were processed

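Gene expression was measured on 4 one-colour Affymetrix arrays of Py-4-1, a mouse hemangioendothelioma cell line, that is, a line from a tumour of endothelial cells. Per the labels, 2 arrays came from control-transfected clones and 2 from clones stably expressing Prox1, with each clone on 1 array. Per the labels' protocols, total RNA was extracted with TRIzol from a nearly confluent culture dish and about 10 µg was turned into biotinylated cRNA. Groups and clone numbers were taken from the sample titles.

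The deposited values are probe set intensities on a linear scale, 1 column per array, and the submitters' processing notes name MAS5, the Affymetrix algorithm that summarises the probes of a probe set into 1 signal. Their version was not given in the sources used here. Intensities ran from 0.156 to 28824 over the 4 deposited columns. The mean of each column after trimming 2% at either end was 500, so that each array had been scaled to the same trimmed mean, and no further normalization was applied. Median intensities were 163 and 177 in control clones 1 and 2 and 179.7 and 173 in the clones labelled as Prox1-expressing. Detection calls were not used here. The number of arrays limits the precision, and an exact permutation test of 2 clones against 2 cannot give a p under 0.333.

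Each array held 22690 probe sets, of which 64 were Affymetrix controls and were left out of the tests. The platform annotation used here paired 20380 of the others with 1 gene, 691 with several and 1555 with none, and genes were named only from the first kind. Of the probe sets with 1 gene, those among the control probe sets included, 20364 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, 29 did not and kept the platform's name, and 0 symbols needed updating. No coordinates are given.

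Values were analysed as log2(intensity + 47), where 47 is the 25th percentile of all values. Fold changes are on this scale, which understates the change of dim probe sets. Probe sets above the median of their array in at least 2 of the 4 arrays were tested, which left 11656 probe sets, 10727 of them with 1 gene, for 6956 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2-sided), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Adjusted p-values of single genes are from this limma fit, except for Prox1, which lay below the filter and was read from the same fit without it. Where a gene had several probe sets, the one with the highest mean log2 value stood for it. Errors of log2 changes are standard errors of the fit, and errors of intensities are SDs of 2 clones.

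A total of 23 gene lists were fixed, among them lymphatic and blood vascular endothelial markers, Notch and arterial genes, angiogenic ligands and receptors, matrix proteases, adhesion, extracellular matrix, mesenchymal markers, the cell cycle and its inhibitors, interferon, chemokine, hypoxia, unfolded protein, cholesterol, serum and TGF-beta responses, ribosomal proteins, and markers of epithelium, leukocytes, hepatocytes and neurons. Lists with at least 5 measured genes were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. List p-values were adjusted over the 19 lists tested, of which 18 are reported here. The same test with the correlation estimated per list, and fry, which tests whether the genes of a list move on balance one way, were run as alternatives. Members of a list were also counted after adjustment over the list alone.

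Genes were named by a fixed rule. Prox1 came first, then the 12 higher and 12 lower genes with the largest changes past the threshold and no overlap between the groups. A direction with fewer such genes was filled up to 12 by the smallest unadjusted p among genes changed at least 2-fold without overlap. From each list up to 4 members past the threshold were taken, or otherwise the 2 with the smallest unadjusted p. Other genes named in the text were chosen after their values were seen.

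The groups, the test, the filter, the lists, the rule for named genes and the alternatives were chosen before the data were examined. Alternatives were quantile normalization, median centring, no pseudocount, a pseudocount of 173 (the median of all values), no filter, a filter at the 75th percentile, no intensity trend, a robust variance model, the clone number as a block, leaving out each clone in turn, leaving out probe sets that can match several transcripts by their suffix, and the mean over all probe sets of a gene for the lists. Leaving out a clone left 1 array in its group. P-values and calls of those fits hold no spread between clones of that group. The procedure was tested on simulated data for the comparison of 2 against 2 clones over 11656 probe sets, 200 of them changed. It recovered 47% of 2-fold and 99% of 4-fold changes, with 8 false calls among 154. A simulated list shift of 0.5 log2 units gave adjusted p = 2.5e-11 with the preset and adjusted p = 0.406 with an estimated correlation. Simulated errors were drawn independently for each probe set and with the same spread in both groups. The simulation therefore does not show how often correlated lists, or groups of unequal spread, give false calls. With an estimated correlation the camera test missed the list shift although the simulated genes were uncorrelated. The estimated correlations of the 7 lists called were 0.310 (cholesterol), 0.294 (blood vascular), 0.208 (lymphatic), 0.203 (angiogenic), 0.183 (unfolded protein), 0.0473 (inhibitors and p53 targets) and -0.0306 (interferon), against the preset of 0.01.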

Results

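The study compared Py-4-1 mouse hemangioendothelioma cells carrying a control plasmid with clones described as stably expressing Prox1, the homeobox transcription factor that specifies lymphatic endothelial identity. Its title concerns the invasion of kaposiform hemangioendothelioma, a vascular tumour. Expression was measured on 4 arrays, 1 for each of 2 control clones and 2 Prox1-labelled clones. The labels describe separate clones with 1 array each. The spread within a group therefore holds differences between clones together with those of culture, RNA and array handling, which cannot be told apart.

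Prox1 itself was measured by 1 probe set (1421336_at), and its intensity was not raised in the clones labelled as Prox1-expressing. Intensities were 52.1 and 60.5 in control clones 1 and 2, and 62.4 and 44.3 in Prox1-labelled clones 1 and 2, with means of 56.3 ± 5.92 (SD, n = 2) and 53.4 ± 12.7. The log2 change was -0.047 ± 0.20 (limma without the intensity filter, adjusted p = 0.963). It turned positive when control clone 2 (0.012) or Prox1-labelled clone 2 (0.083) was left out. The probe set lay below that filter. The highest of 27 Bacillus control probe sets, which match no mouse gene, read 45.3 and 101 in the control clones and 88.4 and 97.5 in the Prox1-labelled clones, and Prox1 exceeded it in control clone 1 alone. Whether the probe set lies in the transfected sequence was not given in the sources used here, and the group names below are those of the labels.

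Py-4-1 cells of both groups carried endothelial transcripts. Pecam1, an endothelial adhesion molecule, read 5679 and 5418 in control clones and 6242 and 5826 in Prox1-labelled clones, and Cdh5, the endothelial cadherin, read 2133 and 4091 against 3340.4 and 3332. The log2 change of Pecam1 was 0.12 (adjusted p = 0.795) and that of Cdh5 was 0.17 (adjusted p = 0.827). Without control clone 1 Cdh5 stood at -0.29, and without control clone 2 at 0.63. Pecam1 and Cdh5, like the others outside the rule for naming, were chosen after their values were seen.

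Against this background, 8 genes differed between the groups, 7 higher and 1 lower in the Prox1-labelled clones. Selp, the adhesion receptor P-selectin of activated endothelium and platelets, rose 4.03-fold, from 946 ± 271 (SD, n = 2) to 3879.6 ± 54.7 (log2 change 2.01 ± 0.22, limma adjusted p = 0.0229). Its other probe set (1449906_at) rose by 2.40 (adjusted p = 0.0298). Car8, a carbonic anhydrase-related protein, rose 4.31-fold, from 408 ± 169 to 1843 ± 33.0 (2.11 ± 0.26, adjusted p = 0.0298). The other probe set of Car8 (1424958_at) rose by 1.33 and did not pass (adjusted p = 0.0904). Idh1, the cytosolic NADP-dependent isocitrate dehydrogenase, rose from 206 ± 12.9 to 807 ± 9.56 (1.75 ± 0.19, adjusted p = 0.0229).

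Tgfb3, a ligand of the TGF-beta family, rose from 13.0 and 20.3 to 189 and 207 (1.95 ± 0.24, adjusted p = 0.0298). Its control intensities lay within the range of the Bacillus control probe sets, and its log2 change was 3.61 without a pseudocount and 0.97 with the larger one. The translation elongation factor gene Eef1a2 rose by 1.67 (adjusted p = 0.0298), the small GTPase gene Gem by 1.85 (adjusted p = 0.0423) and Ctnnal1, which encodes alpha-catulin, by 1.54 (adjusted p = 0.0467). The other probe set of Ctnnal1 (1420929_at) rose by 0.88 and did not pass (adjusted p = 0.147). Ints6, a subunit of the Integrator complex, fell from 2175 ± 249 to 768 ± 4.67 (-1.44 ± 0.19, adjusted p = 0.0352). The dimmer probe set of Ints6 (1423275_at) went the other way, from 170.2 ± 66.9 to 267 ± 24.9 (0.57, adjusted p = 0.359), so the direction for this gene is not settled. The calls of Tgfb3, Gem and Ctnnal1 were lost without a pseudocount, with adjusted p of 0.0695, 0.0598 and 0.0598, and with the robust variance model, in ranges over all alternatives that reached 0.367 without the filter.

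By probe set, 12 of 11656 passed the threshold, 11 higher and 1 lower. Besides the probe sets above, 1450618_a_at, which matches several genes and is not named for any, rose from 25.5 and 21.6 to 430.2 and 708. A pair of probe sets without a gene name here also rose, 1451895_a_at from 17.9 and 22.2 to 365 and 449, and 1424923_at from 221 and 461 to 1704 and 2657. The control signals of 1450618_a_at and 1451895_a_at lay within the range of the Bacillus control probe sets. At an unadjusted p under 0.05 there were 1693 probe sets, 1008 higher and 685 lower, where chance gives 583. Without the intensity filter limma called 0 probe sets, with 2300 at an unadjusted p under 0.05, and under quantile normalization or median centring 4 of the 12 remained, namely 1420558_at of Selp, Idh1, 1450618_a_at and 1451895_a_at. Leaving out a clone raised the count to 133 (control clone 1), 1150 (control clone 2), 42 (Prox1-labelled clone 1) or 67 (Prox1-labelled clone 2), and the 12 remained each time.

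Further genes separated the groups without passing the threshold. Higher in both Prox1-labelled clones were Prss23, a serine protease gene (from 43.6 and 81.3 to 676 and 296, adjusted p = 0.0726), Cyp1b1, a cytochrome P450 (log2 change 1.72, adjusted p = 0.0530), the basement membrane component Nid2 (1.52, adjusted p = 0.0707), the isoprenoid enzyme Idi1 (1.41, adjusted p = 0.0638) and the interferon regulatory factor Irf7 (1.14, adjusted p = 0.0726). Lower in both were the endoplasmic reticulum disulfide isomerase Pdia4 (-1.69, adjusted p = 0.0530), the collagen prolyl hydroxylase subunit P4ha2 (-1.55, adjusted p = 0.0836), Cyb5r1 (-1.49, adjusted p = 0.128), Csn3 (-1.26, adjusted p = 0.0726), the tubulin gene Tubb2a (-1.25, adjusted p = 0.0904) and AU021092 (-1.25, adjusted p = 0.128). Hacd1 (-1.22), Rpl22l1 (-1.14), the chaperone gene Hsph1 (-1.11), the peptidyl-prolyl isomerase gene Fkbp11 (-1.03) and Wdr55 (-1.02) completed this set, with adjusted p-values from 0.0726 to 0.128. The control signals of Prss23 lay under the highest Bacillus control probe set in both control clones, as did 1 signal each of Nid2 (82.1 in control clone 2) and AU021092 (75.8 in Prox1-labelled clone 2), so the size of these changes is uncertain.

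**Figure D1:**
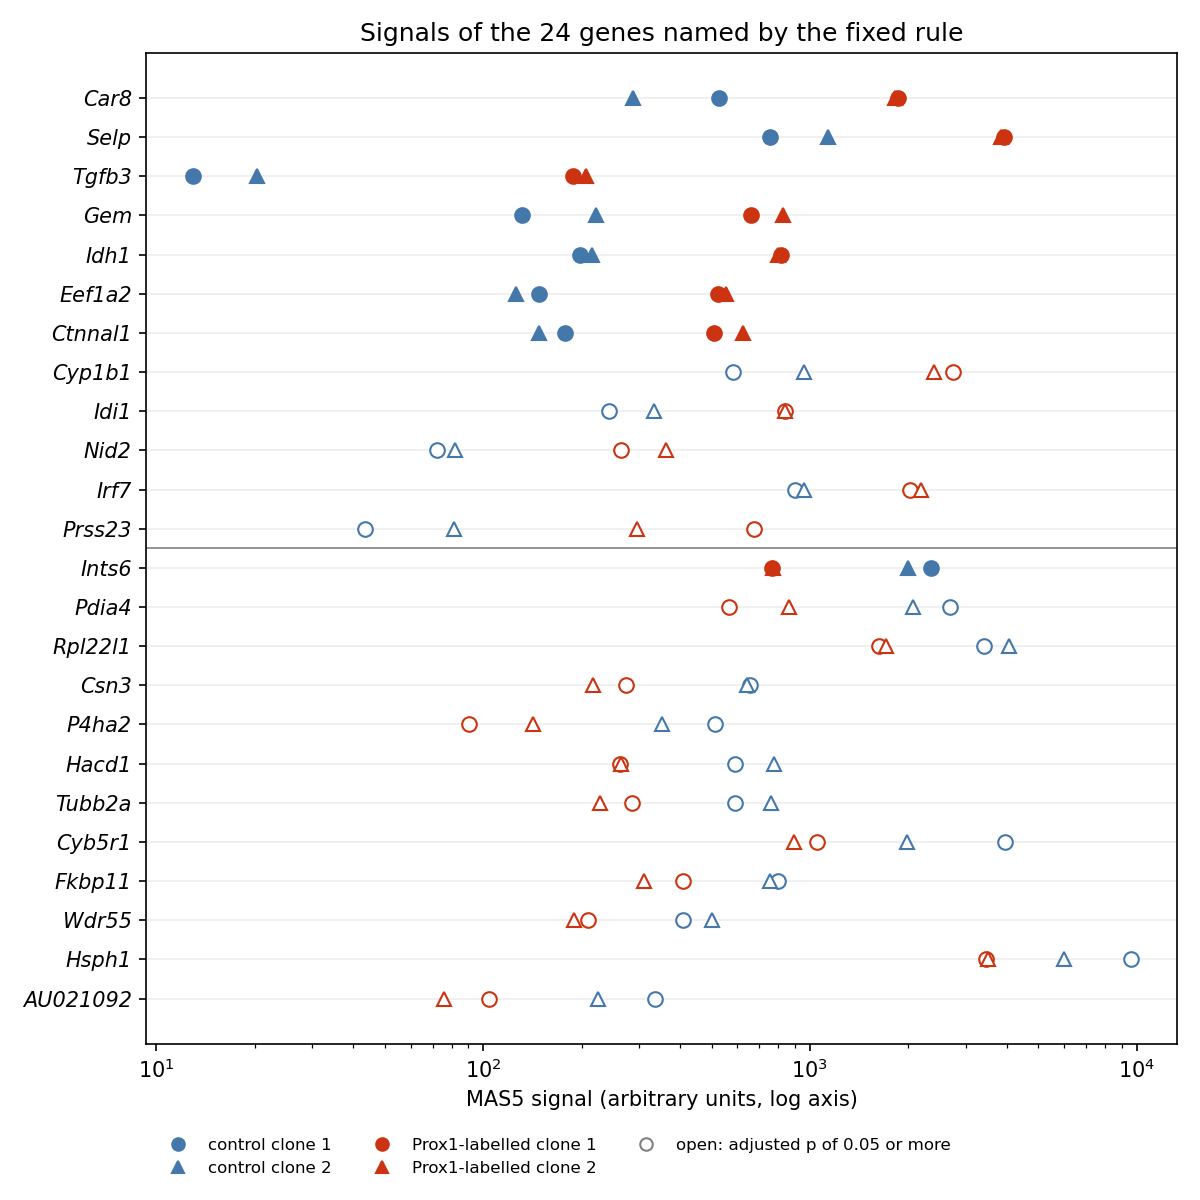
MAS5 signal (arbitrary units, log axis) in each clone of the 24 genes named by the fixed rule, with 12 higher genes above the line and 12 lower genes below it. Blue marks control clones, red Prox1-labelled clones, circles clone 1 and triangles clone 2, and open symbols stand for an adjusted p of 0.05 or more; Selp goes from 754 and 1138 to 3918 and 3841.

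The control clones differed from each other more than the Prox1-labelled clones did. A total of 355 probe sets differed at least 2-fold between control clones 1 and 2, and 60 between the Prox1-labelled clones, with Pearson correlations over probe sets of 0.955 and 0.979 (probe sets are not independent replicates). Between the groups, control clone 1 differed at least 2-fold from the Prox1-labelled clones at 560 and 520 probe sets and control clone 2 at 247 and 201. Group means differed at least 2-fold without overlap at 165 probe sets, 122 higher and 43 lower. Non-overlap of any size was seen in 46.2% of probe sets, where chance gives 33.3%.

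Genes of endothelial identity were higher as groups in the Prox1-labelled clones by camera at the preset correlation. At an estimated correlation 0 of the 18 lists reported were called, here and below. That test also missed the simulated shift of uncorrelated genes, so a call lost there does not show that correlation made it. Of 14 lymphatic endothelial markers measured (32 listed), 11 had a positive log2 change, with a median of 0.39 (camera adjusted p = 0.00375, and adjusted p = 0.556 with an estimated correlation). With adjustment over all genes 0 passed, and adjusted over the list alone 5 rose: the neuropeptide gene Nts (1.22), the hyaluronan receptor Lyve1 (1.22, from 534 and 998 to 1426 and 2204), the scavenger receptor Stab1 (1.06), and the transcription factor genes Foxc2 (0.65) and Nr2f2 (0.57). Without control clone 1 Lyve1 stood at 0.80 and Stab1 at 0.67, and without control clone 2 at 1.65 and 1.45. Flt4, the receptor for VEGF-C, gave 0.38 (adjusted p = 0.403) and its co-receptor Nrp2 gave 0.18 (adjusted p = 0.734). The median was 0.22 without control clone 1 (adjusted p = 0.0409) and 0.14 without the filter, and adjusted p ranged from 0.00191 to 0.0409 over 15 alternatives.

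Of 31 blood vascular endothelial markers (38 listed), 26 had a positive change, with a median of 0.28 (camera adjusted p = 0.000114, and adjusted p = 0.604 with an estimated correlation). Selp was the 1 member past the threshold over all genes. Adjusted over the list alone 5 rose, which were Selp, the VEGF receptor gene Flt1 (1.58, from 42.1 and 182 to 390.5 and 369.7), the angiopoietin receptor gene Tek (0.92), the caveolin gene Cav1 (0.87) and the transcription factor gene Sox17 (0.80). Flt1, with a signal under the highest Bacillus control probe set in control clone 1, ran from 0.90 without control clone 1 to 2.26 without control clone 2. Kdr, the main VEGF receptor gene of endothelium, gave 0.32 (adjusted p = 0.557), with 0.028 without control clone 1 and 0.60 without control clone 2. Without control clone 1 the median was 0.15 and the call was lost (adjusted p = 0.0706), and without control clone 2 the median was 0.58 (adjusted p = 8.9e-07), the ends of the range over 15 alternatives. The list differed between the control clones too, with a median of 0.38 for clone 2 minus clone 1, where the lymphatic list had 0.24.

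Angiogenic ligands and receptors, a list that shares 7 measured members with the blood vascular and 4 with the lymphatic list, had a median of 0.19 with 27 of 35 positive (49 listed, camera adjusted p = 0.0154, and adjusted p = 0.643 with an estimated correlation). Tested over all genes, 0 passed, and adjusted over the list alone 3 rose, Flt1, Tek and the semaphorin receptor gene Plxnd1 (0.92). The call was lost without control clone 1 (median 0.11, adjusted p = 0.148), without Prox1-labelled clone 1 (adjusted p = 0.0975) and without the filter (adjusted p = 0.0533), with adjusted p from 0.00108 to 0.148 over 15 alternatives. Of 15 Notch pathway and arterial genes (23 listed) 10 were positive, with a median of 0.13 (camera adjusted p = 0.571), and 0 passed over all genes or adjusted over the list alone. The Notch ligand gene Dll4 gave -0.74 (adjusted p = 0.246) and Notch4 gave 1.09 (adjusted p = 0.246). Without control clone 1 they stood at -1.0 and 0.50, and without control clone 2 at -0.47 and 1.69.

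**Figure D2:**
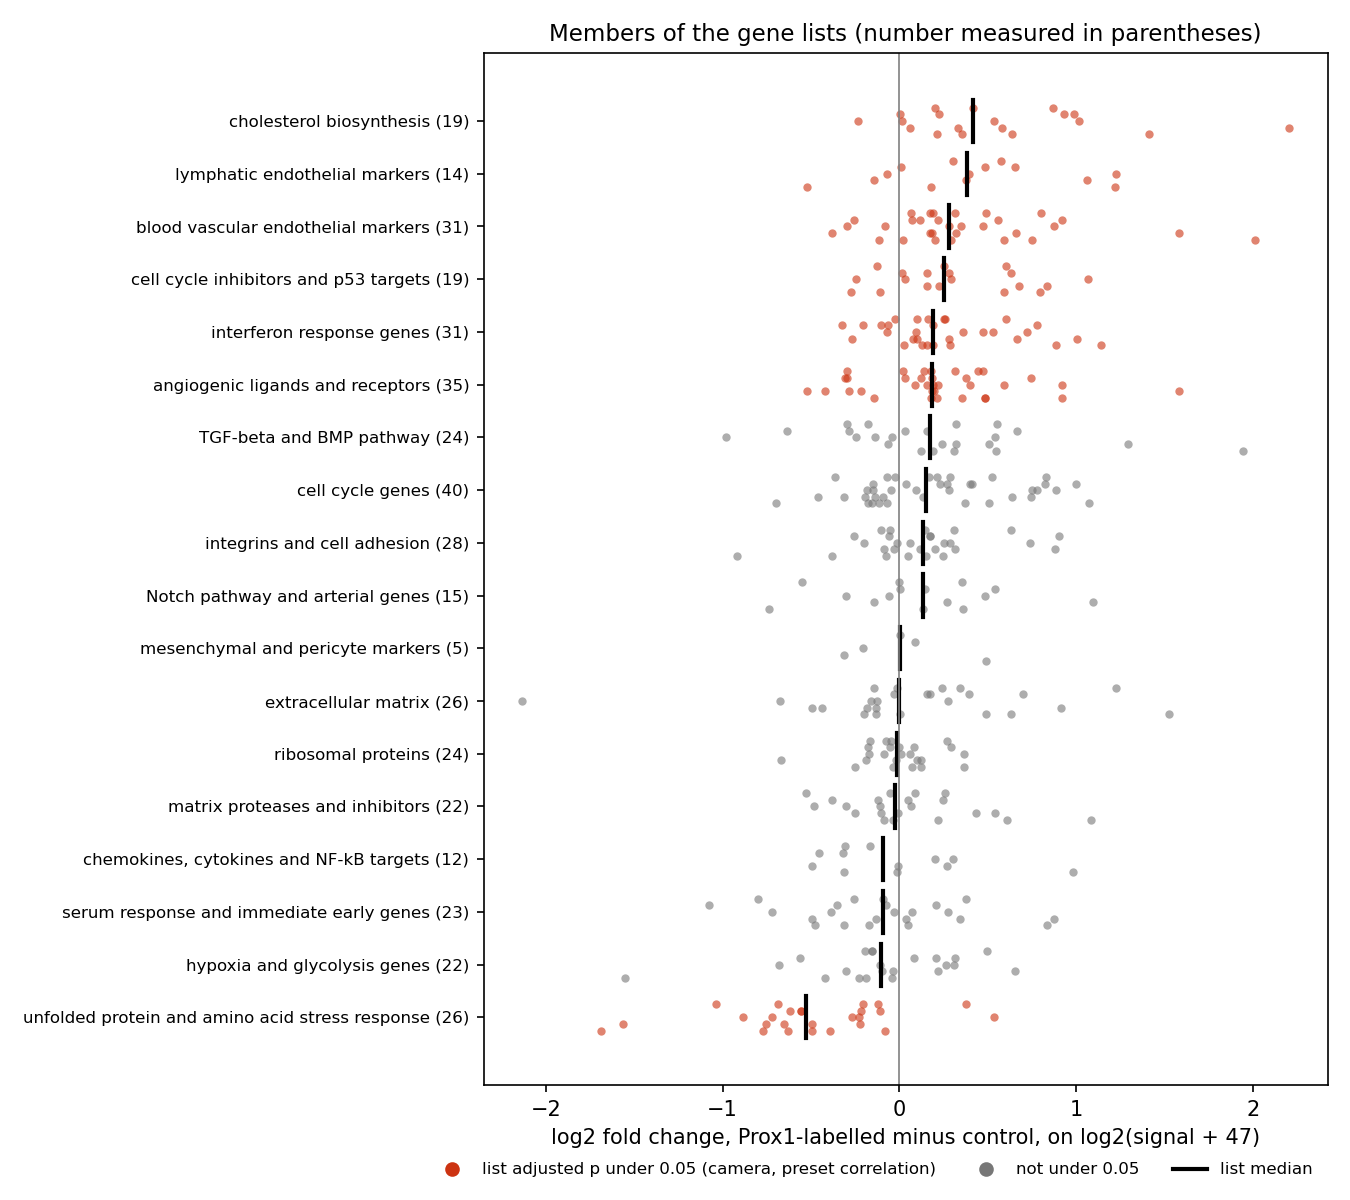
Log2 change (Prox1-labelled minus control, pseudocount 47) of each measured member of 18 gene lists, 1 point per gene, with a bar at the list median and colour for lists with a camera adjusted p under 0.05 at the preset correlation. The unfolded protein list has a median of -0.53 and the cholesterol list 0.42.

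Genes of the unfolded protein and amino acid stress response were lower in the Prox1-labelled clones. All 26 listed genes were measured and 24 had a negative log2 change, with a median of -0.53 (camera adjusted p = 1.7e-07, and adjusted p = 0.553 with an estimated correlation). The endoplasmic reticulum chaperone gene Hspa5, among the brightest on the arrays, went from 25994 and 16709 to 12885 and 12941 (-0.69), and Calr, which encodes calreticulin, from 10334 and 9777 to 6841 and 6259 (-0.62). Over all genes 0 members passed, and adjusted over the list alone 9 fell. These were Hspa5, Calr, Pdia4, the chaperone cofactor gene Sdf2l1 (-1.56), the disulfide isomerase gene Pdia6 (-0.72), the transcription factor gene Xbp1 (-0.56), the cystine transporter gene Slc7a11 (-0.88), the asparagine synthetase gene Asns (-0.63) and Trib3 (-0.75). Without control clone 1 Hspa5 stood at -0.37 and Pdia6 at -0.38, and without control clone 2 at -1.01 and -1.06, while Trib3 ran from -1.03 to -0.48. Between the control clones the list also differed, with a median of -0.35 for clone 2 minus clone 1. The positive members were the stress-induced transcription factor gene Atf3 (0.53, adjusted p = 0.356, from 0.25 to 0.82 on leaving out a clone) and Vldlr (0.38, adjusted p = 0.444, from 0.18 to 0.58).

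Cholesterol biosynthesis genes were higher, with 18 of 19 positive (25 listed) and a median of 0.42 (camera adjusted p = 1.0e-05, and adjusted p = 0.553 with an estimated correlation). Tested over all genes, 0 passed, and adjusted over the list alone 6 rose: the methylsterol oxidase gene Msmo1 (2.20, from 49.6 and 233 to 655 and 769.7), Idi1 (1.41), the farnesyl diphosphate synthase gene Fdps (1.02), the squalene epoxidase gene Sqle (0.93), Nsdhl (0.87) and the lanosterol demethylase gene Cyp51 (0.64). Msmo1 ran from 1.44 without control clone 1 to 2.97 without control clone 2, and Sqle from 0.62 to 1.24. Ebp was the 1 negative member (-0.23). With the stricter filter the median was 0.87, and between control clones 2 and 1 the list differed by a median of 0.39.

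Cell cycle inhibitors and p53 targets were higher, with 15 of 19 positive (25 listed) and a median of 0.25 (camera adjusted p = 0.00375, and adjusted p = 0.553 with an estimated correlation). With adjustment over all genes 0 passed, and adjusted over the list alone 3 rose, the cyclin-dependent kinase inhibitor gene Cdkn1b (0.79), the antiproliferative gene Btg2 (0.83) and the p53 target Trp53inp1 (1.07, or 0.67 without control clone 2 and 1.47 without control clone 1). The call was lost without control clone 2 (adjusted p = 0.145, in a range from 0.000122 over 15 alternatives). The list of 40 cell cycle genes (44 listed) was not called (median 0.15, camera adjusted p = 0.166), with 0 members past either threshold, over all genes or adjusted over the list alone. Its median was -0.12 without control clone 1 (28 of 40 negative, adjusted p = 0.562), and the list was called without control clone 2 (0.36, adjusted p = 0.000227) and without Prox1-labelled clone 2 (0.13, adjusted p = 0.0304). In it Ccnd1, the cyclin D1 gene, gave 0.74 (adjusted p = 0.188) and the replication licensing gene Cdc6 gave -0.70 (adjusted p = 0.185). The proliferation marker Mki67 gave 0.63 (adjusted p = 0.266), in a range from 0.37 without control clone 1 to 0.90 without control clone 2.

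Interferon response genes were higher, with 24 of 31 positive (39 listed) and a median of 0.19 (camera adjusted p = 0.00375, and adjusted p = 0.553 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 2 rose, Irf7 (1.14) and the guanylate-binding protein gene Gbp3 (1.00). Ifit2, an interferon-induced gene, gave 0.72 (adjusted p = 0.174).

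Genes of matrix breakdown, matrix and adhesion, the processes of invasion, were not called as groups. Matrix proteases and their inhibitors had a median of -0.022 over 22 genes measured of 51 listed, 10 of them positive, while the mean (0.052) and the test had the opposite sign (camera adjusted p = 0.887). The median was 0.15 without control clone 2. With adjustment over all genes 0 passed, and adjusted over the list alone 1 rose, the membrane-anchored protease inhibitor gene Reck (1.09, from 104 and 70.0 to 246 and 224). Mmp2, which encodes a gelatinase, gave 0.44 (adjusted p = 0.430), the plasminogen activator gene Plat 0.61 (adjusted p = 0.413), the cathepsin gene Ctsh 0.54 (adjusted p = 0.320) and the inhibitor gene Timp1 -0.48 (adjusted p = 0.338). Without control clone 1 these were 0.21, 0.098, 0.23 and -0.28, and without control clone 2 they were 0.66, 1.12, 0.84 and -0.69.

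Extracellular matrix genes had a median of -0.0034 over 26 genes (51 listed, 13 positive), again with a mean (0.085) and test of the opposite sign (camera adjusted p = 0.312). Over all genes 0 passed. Adjusted over the list alone 4 rose, Nid2 (1.52), Igfbp7 (0.92), the laminin gene Lama4 (0.70) and the collagen gene Col8a1 (1.22, or 0.67 without control clone 1 and 1.78 without control clone 2), and 1 fell, the nidogen gene Nid1 (-0.67). Of 28 integrins and adhesion genes (51 listed) 17 were positive, with a median of 0.13 (camera adjusted p = 0.265) and 0 past the threshold over all genes. On leaving out a clone this median ran from 0.070 to 0.18. Adjusted over the list alone the nectin gene Nectin2 (0.88) and the integrin gene Itgb5 (0.74) rose, 2 in all, and 1 fell, the junctional adhesion gene Jam2 (-0.92).

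Of 24 TGF-beta and BMP pathway genes (36 listed) 15 were positive, with a median of 0.17 (camera adjusted p = 0.0781), and the list was called without Prox1-labelled clone 2 (0.18, adjusted p = 0.0409). Tgfb3 passed over all genes, 1 member, and adjusted over the list alone 2 rose, Tgfb3 and the transcriptional inhibitor gene Id2 (1.29). Mesenchymal and pericyte markers, 5 measured of 23, had a median of 0.0017 (camera adjusted p = 0.887) and 0 passed over all genes or adjusted over the list alone. Vim, which encodes vimentin, gave 0.49 (adjusted p = 0.233) and the smooth muscle actin gene Acta2 gave -0.32 (adjusted p = 0.629), or -0.65 without control clone 1 and 0.020 without control clone 2.

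The remaining lists were not called. Hypoxia and glycolysis genes had a median of -0.11 over 22 of 30 (camera adjusted p = 0.40), with 0 past the threshold over all genes and 1 lower adjusted over the list alone, P4ha2. That list was called without control clone 2 (-0.29, adjusted p = 0.00453) and stood at 0.070 without control clone 1. Egln3, an oxygen-sensing hydroxylase gene, gave 0.65 (adjusted p = 0.220), with 0.89 without control clone 1 and 0.41 without control clone 2. Serum response and immediate early genes had a median of -0.093 over 23 of 26 (camera adjusted p = 0.40), with 0 over all genes and 2 higher adjusted over the list alone, Btg2 and Klf4 (0.87). Chemokines, cytokines and NF-kB targets had a median of -0.092 over 12 of 34 (camera adjusted p = 0.801) and 0 members past either threshold, over all genes or adjusted over the list alone. The chemokine gene Cxcl12 gave 0.98 (adjusted p = 0.229) and Nfkb2 gave -0.49 (adjusted p = 0.493). Without Prox1-labelled clone 1 they stood at 0.45 and -0.95, and without Prox1-labelled clone 2 at 1.52 and -0.037.

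Ribosomal protein genes had a median of -0.012 over 24 of 40 (camera adjusted p = 0.910), with 0 past either threshold, over all genes or adjusted over the list alone. At the preset correlation the list was called in opposite directions without control clone 1 (median 0.14) and without control clone 2 (-0.16). Its estimated correlation was 0.748, against the preset of 0.01, so neither call is taken as a shift between the groups. Rpl22 gave 0.37 (adjusted p = 0.368, from 0.20 to 0.53 on leaving out a clone) and Rps27 gave -0.67 (adjusted p = 0.403). Without control clone 1 Rps27 stood at -0.078, and without control clone 2 at -1.26. Markers of other cell types were mostly below the filter and their lists were not tested. Measured were 3 of 20 epithelial genes, among them Jup (0.32, from -0.13 to 0.78 on leaving out a clone) and Elf3 (-0.042, from -0.33 to 0.25), 3 of 20 leukocyte genes, among them Cd68 (-0.25, from -0.34 to -0.16) and Cd14 (-0.24), 1 of 18 hepatocyte genes, Apoa2 (0.31, from 0.058 to 0.56), and 0 of 16 neuronal genes, with 0 past the threshold.

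**Figure D3:**
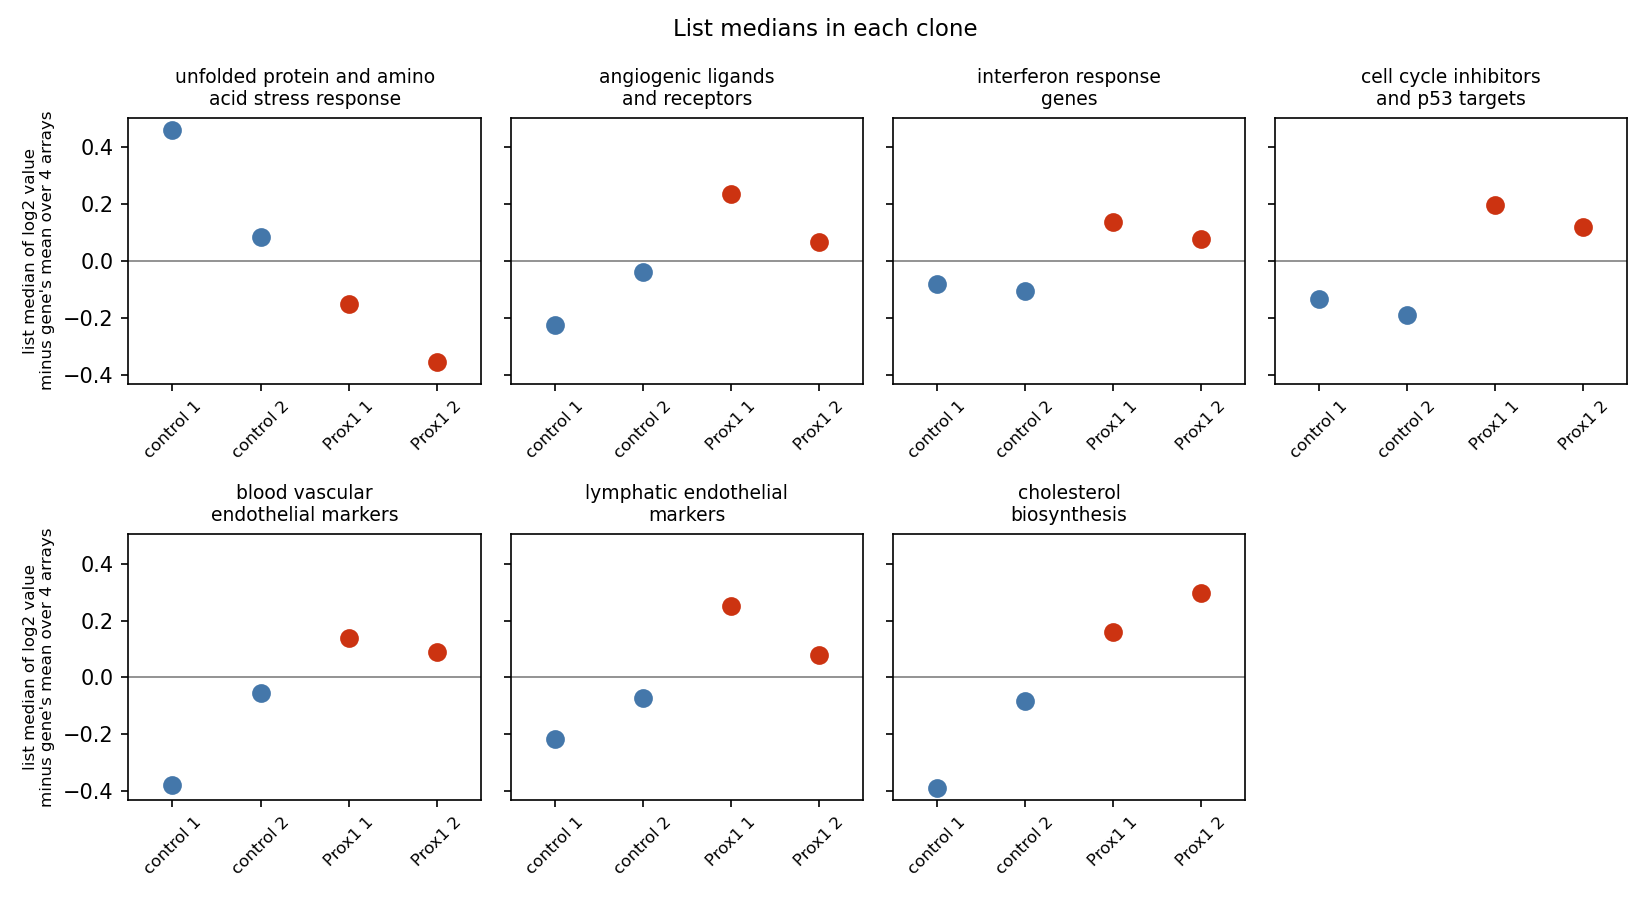
Median over each list's genes of the log2 value (pseudocount 47) minus the gene's mean over the 4 arrays, for the 7 lists reported with a camera adjusted p under 0.05 at the preset correlation, with control clones in blue and Prox1-labelled clones in red. For the unfolded protein list the medians are 0.46 and 0.083 in control clones 1 and 2 and -0.15 and -0.36 in the Prox1-labelled clones.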

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

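All alternatives in this part were planned and none was chosen after the results were seen. Of the 12 probe sets called by limma, 4 remained with quantile normalization (4 called), 4 with median centring (4 called) and 7 with the robust variance model (7 called), and 0 were called without the filter (2300 at an unadjusted p under 0.05), for a cause not tested. The count was 9 to 15 with either other pseudocount, the stricter filter, no intensity trend, or probe sets of several transcripts left out. Leaving out a clone gave 42 to 1150 calls, the 12 included. The lone clone was then assumed to vary like the other group. Without either control clone the spread thus comes from the closely similar Prox1-labelled clones. Control clone 1 differed at least 2-fold from these at 560 and 520 probe sets, and control clone 2 at 247 and 201. With the clone number as a replicate block 110 were called, 78 higher and 32 lower, the 12 included. The deviations of same-numbered clones had a correlation of -0.0091 over probe sets. Whether same-numbered clones shared a day or batch is not given in the labels.

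Over the 8 genes called, those that lost the call were 8 without the filter, 6 with quantile normalization, 6 with median centring, 3 without a pseudocount, 3 with the robust model and 1 (Gem) with the stricter filter, where Tgfb3, Eef1a2 and Ctnnal1 were not tested, all in the same direction, and 0 lost it when a clone was left out. Prox1 ran from -0.18 to 0.083 on leaving out a clone. Probe sets that differed at least 2-fold between control clones numbered 133 with the larger pseudocount, 700 without the filter and 170 with the stricter one. Between Prox1-labelled clones they numbered 126 without a pseudocount, 13 with the larger, 282 without the filter and 10 with the stricter one, and between the groups 260 without a pseudocount, 66 with the larger and 80 with the stricter filter. The cause was not tested beyond what these settings do by construction, as a larger pseudocount shrinks and a smaller one widens the differences of dim probe sets.

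All 7 list calls reported were lost with an estimated correlation and with fry at unchanged medians, which were 0.39 (lymphatic), 0.28 (blood vascular), 0.25 (inhibitors and p53 targets), 0.19 (interferon), -0.53 (unfolded protein), 0.42 (cholesterol) and 0.19 (angiogenic). The interferon call was lost although its estimated correlation (-0.031) lay under the preset of 0.01. Its unadjusted camera p went from 0.00118 to 0.0660. The simulated shift of uncorrelated genes was missed as well (camera adjusted p = 0.406). Losing a call with an estimated correlation thus does not show that correlation between genes made it. Without the filter the angiogenic call was lost (0.17). The unfolded protein, cholesterol, interferon and lymphatic calls held in all 15 other alternatives. Leaving out a clone added calls of the cell cycle, ribosomal, hypoxia and TGF-beta lists. Uncalled lists turned sign with the mean over probe sets (Notch -0.041, extracellular matrix 0.12, ribosomal 0.027), quantile normalization (extracellular matrix 0.012, ribosomal 0.00902), median centring (mesenchymal -0.020) and the larger pseudocount (mesenchymal -0.000642), and the cause was not tested. On leaving out a clone, list medians ran from 0.11 to 0.24 (angiogenic), 0.15 to 0.58 (blood vascular), 0.25 to 0.33 (inhibitors and p53 targets), 0.032 to 0.18 (TGF-beta), -0.12 to 0.36 (cell cycle), -0.23 to 0.19 (chemokines), 0.000641 to 0.15 (extracellular matrix), -0.29 to 0.070 (hypoxia), -0.0044 to 0.15 (matrix proteases), -0.14 to 0.090 (mesenchymal), -0.015 to 0.20 (Notch), -0.16 to 0.14 (ribosomal) and -0.23 to 0.042 (serum response). Single genes that turned sign ran from -0.65 to 0.020 (Acta2), -0.29 to 0.63 (Cdh5), -0.33 to 0.25 (Elf3) and -0.13 to 0.78 (Jup). Signals near the Bacillus control probe sets, as for Prox1, for Tgfb3 and Prss23 in the control clones, and in 1 clone for Flt1, Nid2, AU021092, Reck, Sox17 and Id2, limit what their changes can show.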

Other observations

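All tests in this part were chosen after the results were seen. Control clones 1 and 2 differed from each other in whole groups of genes. Of 40 cell cycle genes 31 read higher in control clone 2, with a median log2 difference of 0.44, at percentile 100 among 10000 random lists matched on expression. Notch pathway and arterial genes were higher there by a median of 0.54 (13 of 15, percentile 99.98), while hypoxia and glycolysis genes had a median of -0.48 (5 of 22 higher, percentile 0) and ribosomal protein genes -0.29 (1 of 24 higher, percentile 0.5). Of the 7 lists called between the groups 3 were about as extreme here, with percentile 100 for blood vascular markers, 99.75 for cholesterol and 0.02 for the unfolded protein list. The others lay at 95.37 (angiogenic), 93.4 (lymphatic), 52.58 (interferon) and 36.11 (inhibitors and p53 targets). These percentiles describe 2 arrays and test no condition, and with 1 array per clone, clone and array handling cannot be told apart. The random lists were drawn gene by gene, so genes that move together reach extreme percentiles more readily. Estimated correlations were 0.273 (cell cycle), 0.260 (Notch) and 0.748 (ribosomal).

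Some single genes differed widely between the control clones. Grb10, an adaptor that binds insulin and growth factor receptors, read 2977 in control clone 1 and 149 in control clone 2, with 421 and 635 in the Prox1-labelled clones. Igfbp3, an insulin-like growth factor binding protein, read 196 and 1844 in control clones 1 and 2, and 4.06 and 420.4 in Prox1-labelled clones 1 and 2. Cd53, a tetraspanin of leukocytes, read 845 and 143 in the control clones and 506 and 678 in the Prox1-labelled clones. These genes were chosen after their values were seen.

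The grouping of the arrays was set against other splits. The 4 arrays can be divided into pairs in 3 ways, too few for a share under 0.05. The real split called 12 probe sets, 1 of the 3 splits reached that number, and the highest of the others called 0, with 195 and 222 probe sets at an unadjusted p under 0.05 against 1693. Each of the other splits sets the closely similar Prox1-labelled clones apart, which puts the difference between the groups into its spread. Low counts there were to be foreseen, so these numbers do not weigh the grouping.

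The first pattern is that Prox1 was not raised in the clones labelled as expressing it. The highest of its 4 signals was 1.41 times the lowest. An exchange of labels between the groups stays open, since a probe set below the intensity filter can read flat under either labelling. A probe set outside the transfected sequence also remains open, as the gene has 1 probe set on this array and no other region could be read. Silencing or loss of the transgene was not tested.

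The second pattern is the lower unfolded protein list. Without control clone 1 its median was -0.38 (95% bootstrap interval over genes -0.46 to -0.19), so the list was also lower against control clone 2. With 1 control array left, no spread between control clones enters. Whether variation between control clones makes up the shift is therefore not decided. After quantile normalization the list's median lay -0.49 from all genes (-0.61 to -0.20), which argues against array scaling. A state that varies between clones or their arrays whatever their label may contribute. The list also differed by -0.35 (-0.69 to -0.044) between control clones 2 and 1. An effect of the transfected gene was not tested apart from this, and the intervals cover genes, taken as independent, not clones.

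The third pattern is the higher lymphatic and blood vascular markers, with a joint median of 0.31. Array scaling is argued against by a median of 0.30 (0.22 to 0.44) above all genes after quantile normalization. Control clone 1 carried much of the shift, as the median went from 0.31 to 0.15 (0.0043 to 0.28) without it. Whether it carries all of the shift stays open, since that interval lies barely above 0 and covers genes, not clones. Variation between clones or their arrays may contribute, since control clone 2 exceeded control clone 1 by 0.35 (0.27 to 0.49) in these genes. An effect of Prox1 on endothelial identity remains an open, untested explanation, as its expression was not seen here.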
